A study of Mus musculus with 14 samples.

How the data were processed

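Transposed DNA of sorted mouse bone marrow cells was sequenced in 14 libraries. The labels place them in 8 groups by cell type (LT-HSC or MPP3) and donor genotype (WT, Dnmt3a, Npm1 or Dnmt3a;Npm1), and groups were taken from the labels alone. Of the groups, 6 hold 2 libraries and 2 hold 1. The deposited file gives a signal value for each of 705361 regions of build mm10 in each library, with a single region set shared by all. Per the submitters' processing notes, DiffBind 2.12.0, edgeR 3.26.4, HOMER 4.10 and R 3.6.0 were used, with no role given. The aligner, the peak caller, the rule that made the common region set, any removal of problem regions and the shift of read ends to the transposase cut were not given in the sources used here.

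The deposited signal values are whole numbers, but they are not raw counts. In 8 libraries the low values lay on multiples of a library-specific step of 1.1 to 2.622, with 99.22% to 99.99% of low values on it, so reads had been multiplied by 1 factor per library and rounded. By these steps the 8 libraries held 7300000 to 18300000 reads in regions. In the other 6 libraries no step was found, and reads could not be recovered for all libraries, so the depth of those 6 is unknown. Library totals of the scaled signal were 14683769 to 28748205, and the median value over tested regions was 71.0 to 390.0. Because the authors' scale factors are not stated, every comparison was made after a further normalization. Where few reads lie behind a value, the step makes small differences unreadable, which the filter on low values was set to limit.

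A count test (the quasi-likelihood test of edgeR) had been planned and was replaced because the values are not counts. Regions with a mean value of at least 100 over all libraries were kept, which left 25129 (3.6%), of median width 1362 bp. No list of known problem regions was applied. Factors from a trimmed mean of M values (TMM) were computed over these regions, and limma was fitted to log2(value/factor + 4), with the 8 groups as the design and a robust, trended prior variance. Lone libraries were assumed to vary like the other groups. Regions were called at a two-sided Benjamini-Hochberg adjusted p under 0.05 within a comparison. With no change, about 0.05 of the 25129 tested regions are due at an unadjusted p under 0.05, so a count near that share is no sign of change. A count far below it can arise where the shared spread is too wide for a comparison, and 0 calls then do not show absence of change. A log2 difference is on the scale of the value plus the pseudocount of 4, so it understates changes of low regions. Errors printed with log2 differences are limma's moderated standard errors, and SDs are over libraries of normalized values. The groups, the 17 comparisons, the 13 gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The filter, the pseudocount, the limma settings and the comparison over all genotypes were chosen after the data were seen and after exploratory fits with other filters and normalizations.

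Genes came from a RefSeq table of the matching assembly, which gives gene bounds without strand. A region was assigned to the gene it lies in or to the nearest gene within 100000 bp, in place of the planned nearest transcription start site, and "gene end" means either bound of a gene. Of the tested regions, 24600 had a gene, 19663 lay in a gene, 12164 within 1000 bp of a gene end and 65 on unplaced contigs. All 412 genes of the lists were in the table and 319 had a tested region. An assigned gene is a label of position; no region was shown to regulate it.

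List tests used camera of limma with the preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Lists cut to 1 region per gene (that of highest mean value) or to gene ends were still tested against all tested regions, a background of another kind. The lists were myeloid, lymphoid, erythroid and megakaryocyte, stem cell identity, Hox and Meis, interferon response, early response, TNF and NF-kB, cell cycle, DNA methylation and chromatin, genes cooperating in acute myeloid leukaemia, mast cells with basophils and eosinophils, and niche cells. Named regions were, for comparisons against WT, between cell types and of Dnmt3a;Npm1 with Dnmt3a, the 6 higher and 6 lower called regions of smallest p whose libraries did not overlap, 1 per gene; for the other comparisons, 4 in each direction. Where fewer than 5 were called, all of them and the 3 of smallest p in each direction were taken as not past the threshold. Up to 3 genes per list were taken by smallest p, and the Dnmt3a, Npm1, Hoxa9, Hoxa10, Meis1 and Cebpa regions always. Overlap with shared controls was set against 20 simulations of unchanged groups.

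The fit was tested on simulated data with known changes for 6 comparisons, in 3 runs each over 25129 regions. The interactions, the cell type differences, the Dnmt3a comparisons in MPP3, the averaged effects other than that of Npm1 in LT-HSC, and the comparisons of Dnmt3a;Npm1 were not simulated. For LT-HSC Npm1 against WT, 0.5%, 7.0% and 62.1% of regions changed by 1.5, 2 and 4-fold were called, and 9.2% of calls were false. For LT-HSC Dnmt3a against WT, with 1 library, 34.3% of 4-fold changes were called. For the Npm1 effect averaged in LT-HSC, 23.9% of 2-fold and 85.4% of 4-fold changes were called, and for all MPP3 against all LT-HSC libraries 58.7% and 98.0%, with 4.5% of calls false. A list shifted by 0.3 was called in 3 of 3 runs in each of the 6 comparisons, with regions simulated as independent of each other. Apart from the set changes and a scale factor, simulated libraries differed only by noise, with a spread per region shared by all of them. Differences in enrichment or background between libraries were not simulated, so the shares of false calls do not cover calls that these could cause.

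Alternatives were other normalizations (median-ratio factors, library total, loess, quantile, deposited scale), other filters and pseudocounts, library weights, background subtraction with a pseudocount of 16, library enrichment as a covariate, the replicate letter as a block, other thresholds, each cell type's own libraries, and each library left out in turn. A correction for GC content and tests of motif enrichment need a genome sequence, which was not used here. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the R package data.table (1.17.8).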

Results

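Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 14 mouse libraries from sorted bone marrow cells. Long-term haematopoietic stem cells (LT-HSC), which sustain blood formation, and MPP3 cells, a multipotent progenitor population biased towards myeloid output, each gave 7 libraries. Donor marrow was wild type carrying the Mx-Cre transgene (WT) or heterozygous for a conditional Dnmt3a R878H allele, a conditional Npm1 allele or both. The labels write the Dnmt3a allele as flR878H and the Npm1 allele as frt. Irradiated recipients received 1000000 marrow cells. Poly(I:C), which induces interferon and so the Mx1 promoter that drives Cre, was given 4 weeks later, tamoxifen 4 weeks after that, and marrow was taken after a further 4 weeks. Of the 8 groups, 6 held 2 libraries. LT-HSC Dnmt3a and MPP3 Dnmt3a;Npm1 held 1 library each and so gave no replicate spread of their own. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

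The total signal over 705361 regions was 27928444 and 21957346 in LT-HSC WT, 21991141 in LT-HSC Dnmt3a, 17412782 and 14683769 in LT-HSC Npm1, and 20122810 and 25835797 in LT-HSC Dnmt3a;Npm1. In MPP3 it was 18304254 and 28748205 in WT, 19208148 and 21044058 in Dnmt3a, 18739535 and 23512341 in Npm1, and 20382565 in Dnmt3a;Npm1. Tests used the 25129 regions with a mean value of at least 100. The share of signal in those regions differed between groups. It was 44.8% and 30.0% in LT-HSC WT but 19.5% and 15.7% in LT-HSC Npm1, and 38.2% in LT-HSC Dnmt3a. LT-HSC Dnmt3a;Npm1 stood at 31.3% and 30.7%. In MPP3 the shares were 29.8% and 51.6% in WT, 22.3% and 26.6% in Dnmt3a, 32.6% and 44.7% in Npm1, and 35.8% in Dnmt3a;Npm1. The main principal component held 27.6% of the variance and placed the LT-HSC Npm1 libraries at 81.1 and 87.0. MPP3 Dnmt3a came next, at 38.4 and 12.3, and MPP3 WT replicate B stood at the opposite end, at -57.2. The order of the libraries along it closely followed, in reverse, their share of signal in tested regions, across genotypes and cell types.

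**Figure D1:**
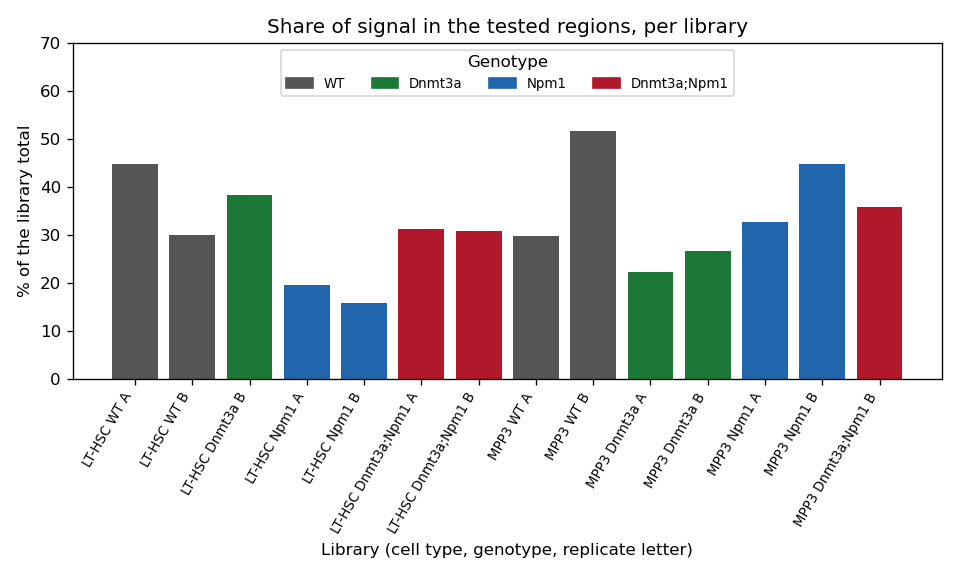
Each bar is the signal in the 25129 tested regions as a percentage of the library's total over all regions, coloured by genotype. The LT-HSC Npm1 bars, at 19.5% and 15.7%, are the shortest, and that of MPP3 WT replicate B, at 51.6%, is the tallest.

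The loci of the mutated genes were examined before the comparisons. The tested region at Npm1 (chromosome 11, 33161861 to 33163699, mm10), a gene for a nucleolar protein, differed by 0.08 on the log2 scale (SE 0.33, n = 2 and 2) between Npm1 and WT LT-HSC and by 0.18 (SE 0.33, n = 2 and 2) in MPP3. At Dnmt3a, a DNA methyltransferase gene, both regions within 1 kb of a gene end had a mean value of at most 46.2 and were not tested. Accessibility at neither locus reports whether an allele recombined, so these values do not check the genotype labels. Of the genes fixed in advance, Hoxa9 (2 regions), Hoxa10 (3), Meis1 (12) and Cebpa (3) had no region past the threshold in any of the 17 planned comparisons with limma. The smallest adjusted p among them was 0.108, at Meis1. Hoxa9, Hoxa10 and Meis1 encode homeodomain proteins active in stem cells and in leukaemia with mutant NPM1, and Cebpa encodes a myeloid transcription factor.

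WT MPP3 and WT LT-HSC were compared to ask how the sorted populations differ without a mutation. Regions of the myeloid list lay higher in MPP3, with a median log2 difference of 0.34 over 69 regions, 52 of them positive (camera adjusted p = 2.8e-08, adjusted p = 0.00629 with an estimated correlation). Its leading members were Ctsg, which encodes the granule protease cathepsin G (3.46, SE 0.72), Mpo, the myeloperoxidase gene (2.03, SE 0.48), and Gfi1, a granulocyte transcription factor gene (1.75, SE 0.46, n = 2 and 2 for each). Regions of the Hox and Meis list lay lower, with a median of -0.46 and 7 of 52 positive (camera adjusted p = 3.8e-10, adjusted p = 0.0884 with an estimated correlation), with Nkx2-3 at -1.60 (SE 0.33). The erythroid and megakaryocyte list had a median of -0.25 with 14 of 58 positive (camera adjusted p = 3.1e-04, adjusted p = 0.0163 with an estimated correlation), its leading members being the GATA1 cofactor gene Zfpm1 (-1.70, SE 0.49) and the platelet receptor gene Gp1ba (-1.47, SE 0.45). The stem cell identity list had a median of -0.17 (camera adjusted p = 0.00932, adjusted p = 0.135 with an estimated correlation), with Tie1 at -1.10 (SE 0.42) and Gata2 at -0.80 (SE 0.32), while the Runx1 region of smallest p went the other way, at 1.36 (SE 0.51).

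Among single regions of this comparison, limma called 0 at an adjusted p under 0.05, and 1435 had an unadjusted p under 0.05. The smallest p values belonged to a region overlapping the adjoining Mpo and Lpo genes (chromosome 11, 87803850 to 87810872, 2.21, SE 0.38, adjusted p = 0.161), to Atp9b (1.90, SE 0.34) and Mapk4 (2.41, SE 0.45) on the higher side, and to Nkx2-3, Cdh23 (-1.81, SE 0.38) and Pik3ap1 (-1.91, SE 0.41) on the lower side. With simulated changes of 4-fold, 60.6% were recovered in this comparison. Without MPP3 WT replicate B the erythroid and megakaryocyte list had an adjusted p of 0.0647 and the stem cell list of 0.182, and without LT-HSC WT replicate B the latter had 0.107. Without MPP3 WT replicate A their medians were -0.46 and -0.27, and without replicate B -0.15 and -0.04. Without LT-HSC WT replicate A, 13 regions were called, and without either MPP3 Dnmt3a library 3.

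All 7 MPP3 libraries were then set against all 7 LT-HSC libraries, as the mean of the 4 genotypes, a comparison added after the data were seen. It called 103 regions, 62 higher and 41 lower in MPP3 (limma, 3768 at an unadjusted p under 0.05). The lower regions included those at Nkx2-3 (chromosome 19, 43598869 to 43601813, 10512 bp from the gene, -1.53, SE 0.18, adjusted p = 0.00162), Obsl1 (chromosome 1, 75505052 to 75507387, -1.24, SE 0.18) and Zfpm1 (chromosome 8, 122308957 to 122310156, inside the gene, -1.73, SE 0.27). Others were at Plpp7 (-1.37, SE 0.23) and Prkg1 (-1.09, SE 0.19). A region at Tcf15, a transcription factor gene of quiescent stem cells, was lower as well (-0.96, SE 0.19, adjusted p = 0.0316). Higher regions included Gm5820 inside Arhgap26 (1.97, SE 0.28, adjusted p = 0.00908), Rgs3 (chromosome 4, 62660442 to 62662836, 0.99, SE 0.17), Filip1 (chromosome 9, 79815559 to 79816913, 1.39, SE 0.25) and Ldlrad4 (chromosome 18, 68159242 to 68161232, 1.07, SE 0.19). The granule genes Mpo (chromosome 11, 87789484 to 87791056, 1.38, SE 0.27, adjusted p = 0.0281) and Prtn3 (0.74, SE 0.16, adjusted p = 0.0483) were also called higher.

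The list tests of this comparison are not independent of those in WT cells, since it includes the same 4 WT libraries. The median was 0.22 for the myeloid list, with 2 regions called and 13 when adjusted over the list alone (camera adjusted p = 1.3e-04, adjusted p = 0.0195 with an estimated correlation). It was -0.31 for the Hox and Meis list, with 2 called and 8 when adjusted over the list alone (camera adjusted p = 2.9e-08, adjusted p = 0.1 with an estimated correlation). The erythroid and megakaryocyte list stood at -0.33 (camera adjusted p = 3.5e-05, adjusted p = 0.0164 with an estimated correlation) and the stem cell list at -0.19 (camera adjusted p = 1.3e-04, adjusted p = 0.0518 with an estimated correlation). Most called regions lay away from gene ends: 4.8% of the higher and 22% of the lower ones were within 1 kb of one, against 48.6% of uncalled regions. Scaled to the library total, the stem cell list median was 0.01 where all regions stood at 0.21, and with background subtracted it was 0.02 where they stood at 0.17. The count was 1 without LT-HSC Npm1 replicate A, 57 without its replicate B, 27 without LT-HSC WT replicate B and 166 without LT-HSC Dnmt3a;Npm1 replicate A. Among MPP3 libraries it was 10 and 2 without WT replicates A and B, 3 and 9 without Npm1 replicates A and B, and 545 and 438 without Dnmt3a replicates A and B. With library enrichment as a covariate 20 regions were called, with background subtracted 0 (limma, 2869 at an unadjusted p under 0.05), and scaled to the library total 354 were called higher and 39 lower.

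**Figure D2:**
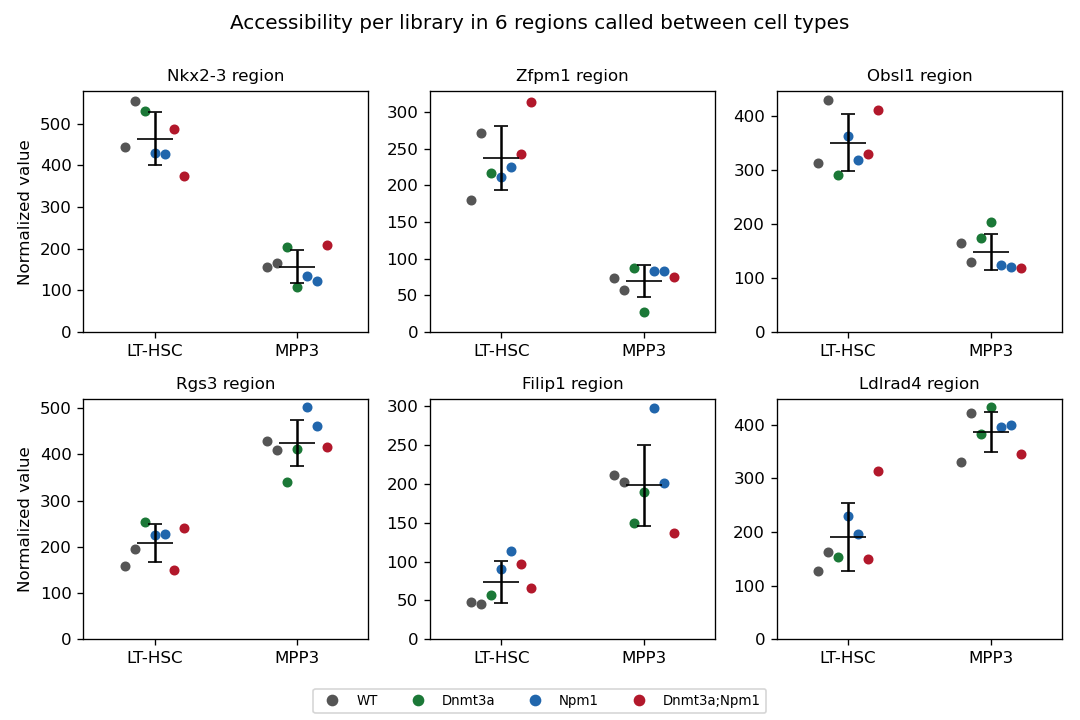
Each point is 1 library's TMM-normalized value, coloured by genotype, in 6 regions called between the 7 LT-HSC and the 7 MPP3 libraries; horizontal marks are means and bars are SDs over the 7 libraries. In the Nkx2-3 region the means were 463.9 in LT-HSC and 157.1 in MPP3. The libraries of the cell types do not overlap in these regions because the rule for named regions required it. Of all called regions, 26 of the 62 higher and 29 of the 41 lower ones did not overlap.

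The effect of the Npm1 mutation alone in LT-HSC gave the largest number of single-region calls among the planned comparisons, 1218, of which 576 were higher and 642 lower than in WT (limma, 5973 at an unadjusted p under 0.05, n = 2 and 2). Higher regions included several of the myeloid list: Ctsg (chromosome 14, 56105001 to 56106120, 3.10, SE 0.72, adjusted p = 0.0217), a region 49488 bp from Irf8, a monocyte and dendritic cell transcription factor gene (chromosome 8, 120806182 to 120808535, 2.10, SE 0.44, adjusted p = 0.0155), and Igsf6 (1.61, SE 0.40, adjusted p = 0.0278). In this list 8 regions were called, all higher, 10 when adjusted over the list alone, and the median was 0.37 with 52 of 69 positive (camera adjusted p = 7.0e-04, adjusted p = 0.0434 with an estimated correlation). Markers of other lineages had medians as high without passing, the lymphoid list 0.40 with 39 of 47 positive (camera adjusted p = 0.158) and the mast cell, basophil and eosinophil list 0.53 with 7 of 11 positive (camera adjusted p = 0.324). Also higher were Hdc, which encodes the enzyme that makes histamine (2.69, SE 0.54, adjusted p = 0.0146), a region near Notch1 (2.31, SE 0.55), Cd83 (1.22, SE 0.35), Pdgfrb (1.34, SE 0.38) and a region 15926 bp from the interferon receptor gene Ifnar1 (1.86, SE 0.49). The 6 higher regions of smallest p were a region inside Tbc1d8 (chromosome 1, 39449466 to 39450898, 3.33, SE 0.47), a region 87151 bp from Vmn1r2 (2.26, SE 0.30), and 4 regions of the unplaced contig JH584304 with differences from 2.17 to 2.44.

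The lower regions of this comparison were mostly at gene ends. By smallest p they were Stard13 (chromosome 5, 151367829 to 151369331, -2.15, SE 0.28, adjusted p = 0.00207), Sec62, a gene of protein import into the endoplasmic reticulum (chromosome 3, 30792581 to 30794103, -2.0, SE 0.30, adjusted p = 0.0034). After them came Zbed4 (-1.59, SE 0.26), Zfp644 (-1.77, SE 0.30), N4bp2l2 (-1.58, SE 0.27) and Zbtb5 (-1.70, SE 0.30). Early response transcription factor genes were among them, with Klf6 at -1.23 (SE 0.26), Nr4a3 at -1.43 (SE 0.32) and Maff at -1.06 (SE 0.27), but of the 9 called regions of that list 4 were higher, and its median was -0.07. So were the cell cycle genes Ccnd2 (-1.06, SE 0.25), Cdk1 (-1.27, SE 0.30) and Ccnb1 (-1.15, SE 0.32), and the chromatin and metabolic genes Ezh2 (-1.08, SE 0.26), Asxl2 (-1.27, SE 0.24) and Idh1 (-1.33, SE 0.25). Nfe2, a megakaryocyte transcription factor gene (-1.33, SE 0.28), the P-selectin gene Selp (-1.23, SE 0.32), Mcl1 (-0.97, SE 0.25), Smc3 (-1.20, SE 0.33), Ifngr1 (-1.23, SE 0.32), Mx1 (-1.49, SE 0.41) and a region near Klrb1c (-1.67, SE 0.35) were also called lower. Neither the Hox and Meis list nor the stem cell identity list had a called region, and the early response, cell cycle and chromatin lists did not pass, with adjusted p values of 0.718, 0.328 and 0.328.

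The called regions of this comparison differed in kind by direction. The lower regions had a median value of 567.4 and 76.6% lay within 1 kb of a gene end, whereas the higher regions had a median value of 143.6, 24.5% lay near a gene end and 53 of the 65 tested regions on unplaced contigs were among them. Median differences were -1.18 and 2.03. The LT-HSC Npm1 libraries had the lowest shares of signal in tested regions, as given above, and 0 regions were called once library enrichment was a covariate (limma, 1186 at an unadjusted p under 0.05). Loess normalization called 175 regions (141 higher, 34 lower), scaling to the library total 11336 (151 higher, 11185 lower) and background subtraction 2077 (212 higher, 1865 lower). The count was 84 and 266 without LT-HSC WT replicates A and B, 555 and 148 without LT-HSC Npm1 replicates A and B, 2145 and 2152 without MPP3 Dnmt3a replicates A and B, and 660 and 640 without MPP3 Npm1 replicates A and B. The myeloid list passed with that covariate (0.32, adjusted p = 0.0197) but not with 1 region per gene (adjusted p = 0.146) or with background subtracted (adjusted p = 0.0856). With background subtracted its median was -0.52 where all regions stood at -0.83, and scaled to the library total it was -0.76 where all regions stood at -1.14. Without LT-HSC Npm1 replicate A the list median was 0.57.

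Averaged over both Dnmt3a states, the Npm1 mutation in LT-HSC gave 46 called regions, 44 higher and 2 lower (limma, 3906 at an unadjusted p under 0.05, 4 against 3 libraries). The higher regions of smallest p were 2 on contig JH584304 (1.51, SE 0.23, and 1.56, SE 0.26), one inside Zc3h7a (chromosome 16, 11143937 to 11144403, 1.18, SE 0.18, adjusted p = 0.0297) and the region 87151 bp from Vmn1r2 (1.46, SE 0.24). Ctbs, a lysosomal chitobiase gene, was lower (chromosome 3, 146449965 to 146451179, -1.09, SE 0.22, adjusted p = 0.0495). The myeloid list had a median of 0.28, with 1 region called and 50 of 69 positive (camera adjusted p = 3.8e-04, adjusted p = 0.0367 with an estimated correlation). Its median was -0.43 when scaled to the library total, where all regions stood at -0.74, and -0.17 with background subtracted, where they stood at -0.46. The lymphoid list had a median of 0.27 with 36 of 47 positive and did not pass (camera adjusted p = 0.0969). With library enrichment as a covariate the myeloid list passed (0.20, adjusted p = 0.00937), and with 1 region per gene its adjusted p was 0.278. Of the 44 higher regions, 19 lay on unplaced contigs, and with those contigs left out 0 regions were called (3858 at an unadjusted p under 0.05). Known problem regions were not removed, so artefact signal was not excluded for the contig and Zc3h7a regions. Scaled to the library total, 60 regions were called higher and 5179 lower. With library enrichment as a covariate 0 were called (limma, 794 at an unadjusted p under 0.05), with background subtracted 0 (3203), with loess 17 and with the replicate letter as a block 20. The count was also 0 without LT-HSC WT replicate A or any 1 of the LT-HSC Npm1 and Dnmt3a;Npm1 libraries, and 118 and 122 without MPP3 Dnmt3a replicates A and B. When the Npm1 mutation was added to the Dnmt3a mutation in LT-HSC, limma called 0 regions, with 670 at an unadjusted p under 0.05 (n = 2 and 1), and the smallest p values were at Noxa1 (2.55, SE 0.58), Col19a1 (3.09, SE 0.70) and Ptprn (1.67, SE 0.39), each with an adjusted p of 1. There, 12 regions were called without LT-HSC Dnmt3a;Npm1 replicate A.

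For the Dnmt3a mutation alone in LT-HSC, limma called 0 regions, with 332 at an unadjusted p under 0.05 (n = 1 and 2). The regions of smallest p were Krt78 (2.56, SE 0.65), Dhx15 (2.07, SE 0.57) and Tmem117 (1.84, SE 0.52) on the higher side and Col19a1 (-2.94, SE 0.70), Bahcc1 (-2.40, SE 0.60) and Rab11fip4 (-3.07, SE 0.79) on the lower side, each with an adjusted p of 1. With both mutations against WT in LT-HSC, 1 region was called, on chromosome Y (90811679 to 90813205, 66596 bp from Gm52481), lower by log2 -2.43 (SE 0.35, limma adjusted p = 0.0253, n = 2 and 2, 1484 regions at an unadjusted p under 0.05). The sex of the donors is not given in the sources used here, so a difference in sex between groups was not excluded. Every library had signal in this region, and whether its sequence is specific to chromosome Y was not examined. Its values therefore do not report donor sex. The same region was the only call for the Dnmt3a mutation averaged over both Npm1 states in LT-HSC (-1.86, SE 0.28, adjusted p = 0.0386, 2626 at an unadjusted p under 0.05). Not called beside it were Gramd1b (3.89, SE 0.68, adjusted p = 0.154) with both mutations, and Lrrc8d (1.24, SE 0.21) and Bin1 (-2.47, SE 0.43), each with an adjusted p of 0.099, in the average. The lymphoid list had a median of -0.28 in that average (camera adjusted p = 0.0183, adjusted p = 0.365 with an estimated correlation). That list stood at 0.17 when scaled to the library total, where all regions stood at 0.47, and it did not pass with loess (-0.10, adjusted p = 0.335), library enrichment as a covariate (-0.10, adjusted p = 0.691), background subtracted (0.01, adjusted p = 0.2), 1 region per gene (-0.12, adjusted p = 0.829) or near gene ends (-0.31, adjusted p = 0.0646). Its adjusted p was 0.0558 without LT-HSC WT replicate B, 0.158 without LT-HSC Npm1 replicate B and 0.0629 without LT-HSC Dnmt3a;Npm1 replicate B, and its median was -0.43 without replicate A of that group. Both calls of the chromosome Y region were lost without LT-HSC WT replicate B, either LT-HSC Npm1 library or LT-HSC Dnmt3a;Npm1 replicate B, and that of the average also without either MPP3 WT library. With the replicate letter as a block (2205 at an unadjusted p under 0.05) or library enrichment as a covariate (710), limma called 0 regions in the average, and with loess (1657) or background subtracted (442) it called 0 with both mutations. Without LT-HSC Dnmt3a;Npm1 replicate A, 99 regions were called with both mutations and 37 in the average, and without LT-HSC WT replicate A, 4 with both mutations.

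In MPP3, the Dnmt3a mutation went with higher values over the Hox and Meis list, with a median of 0.37 and 39 of 52 regions positive (camera adjusted p = 1.8e-04, adjusted p = 0.892 with an estimated correlation). The members of smallest p were Hoxb6 (1.61, SE 0.48), Hoxa5 (chromosome 6, 52203222 to 52204967, 1.16, SE 0.35) and Hoxb8 (1.77, SE 0.54, n = 2 and 2), none of them called. Averaged over both Npm1 states, the list had a median of 0.25 with 38 of 52 positive and 1 region past the threshold when adjusted over the list alone (camera adjusted p = 4.9e-06, adjusted p = 0.318 with an estimated correlation), and Hoxa5 stood at 1.48 (SE 0.28). Over all tested regions limma called 0 for the Dnmt3a mutation alone, with 2548 at an unadjusted p under 0.05, and 0 for the average, with 1215. The smallest p values were at Plekha2 (-3.0, SE 0.51), E130308A19Rik (-2.13, SE 0.36) and Ano8 (-2.06, SE 0.35), each with an adjusted p of 0.0753, and the higher side included Coro1b (2.08, SE 0.44). The share of signal in tested regions was lower in MPP3 Dnmt3a, at 22.3% and 26.6%, than in MPP3 WT, at 29.8% and 51.6%. Scaled to the library total, the list medians were -0.36 and -0.14 where all regions stood at -0.75 and -0.41. With background subtracted they were 0.09 (adjusted p = 0.0384) and 0.08 (adjusted p = 9.1e-04) where all regions stood at -0.27 and -0.13. For the Dnmt3a mutation alone, without MPP3 Dnmt3a replicate A the list had an adjusted p of 0.0806 and 128 regions were called, against 368 without replicate B and 34 without MPP3 WT replicate A. For the average, 5 regions were called without MPP3 Dnmt3a replicate B and 2 without MPP3 WT replicate A.

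The Npm1 mutation alone in MPP3 gave 0 calls with limma and 31 regions at an unadjusted p under 0.05 (n = 2 and 2). That count is far below 0.05 of the 25129 tested regions, so the 0 calls do not show that nothing changed. The region at an end of Mx1, an interferon-induced gene (chromosome 16, 97462728 to 97465500), had the smallest p (-2.43, SE 0.41, adjusted p = 0.241), and its means were 130.7 (SD 21.2) in Npm1 and 796.3 (SD 491.5) in WT. Without MPP3 WT replicate B, 1 region was called. Both mutations against WT in MPP3 gave 0 calls with limma and 98 at an unadjusted p under 0.05 (n = 1 and 2), with Fam178b at 1.80 (SE 0.64) and Vamp2 at -1.09 (SE 0.35). Adding the Npm1 to the Dnmt3a mutation in MPP3 gave 0 calls with limma and 1418 at an unadjusted p under 0.05 (n = 1 and 2). There, Pparg, a nuclear receptor gene (2.81, SE 0.53), Gfod1 (3.29, SE 0.63) and Clec16a (3.38, SE 0.70) stood highest by p, and Camk1d (-2.0, SE 0.35), Cdk8 (-1.71, SE 0.33) and Axin2 (-1.92, SE 0.37) lowest. Camk1d, Cdk8 and Axin2 were each higher in the LT-HSC Npm1 and MPP3 Dnmt3a libraries than in any other (Axin2 at least 2708.8 against at most 2355.4). Those libraries had the lowest shares of signal in tested regions, so an effect of enrichment on these regions was not excluded. The Zc3h7a and Filip1l regions, named for other comparisons, had their highest values in LT-HSC Npm1. The named regions of contig JH584304 shared the library pattern of Camk1d, Cdk8 and Axin2. Known problem regions were not removed, so artefact signal was not excluded for any of these. The Hox and Meis list had a median of -0.33 in that step (camera adjusted p = 0.0472, adjusted p = 0.686 with an estimated correlation) and of -0.18 for the Npm1 effect averaged over both Dnmt3a states (camera adjusted p = 0.00638, adjusted p = 0.535 with an estimated correlation). The average called 0 regions with limma, and 707 had an unadjusted p under 0.05. Scaled to the library total, these list medians were 0.28 and 0.10 where all regions stood at 0.65 and 0.30. Without MPP3 Dnmt3a replicates A and B, 26 and 118 regions were called in the added step and 3 and 13 in the average, and the list had adjusted p values of 0.804 and 0.051 in the added step. In the average the list had 0.305 without replicate A and 0.278 with background subtracted. In the added step it did not pass with the replicate letter as a block (-0.26, adjusted p = 0.29), scaled to the library total (adjusted p = 0.186), with loess (-0.28, adjusted p = 0.0681), with library enrichment as a covariate (-0.21, adjusted p = 0.198) or with background subtracted (-0.05, adjusted p = 0.392). In the added step the list also missed the threshold without either LT-HSC WT library, although its median stayed at -0.33. It missed it as well without either LT-HSC Npm1, MPP3 WT or MPP3 Npm1 library.

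The series title names cooperativity of the mutations, which on the log2 scale is the departure of the double mutant from the sum of the single effects. In LT-HSC limma called 0 regions for this interaction, with 1766 at an unadjusted p under 0.05, and in MPP3 0, with 573. In LT-HSC the smallest p values were at Stard13 (2.13, SE 0.44), Gmds (2.00, SE 0.44) and Zfp644 (2.11, SE 0.47) on the higher side, and Ccdc88c (-3.63, SE 0.76), Osbpl8 (-4.36, SE 0.92) and Krt78 (-3.79, SE 0.84) on the lower side, each with an adjusted p of 0.666. In MPP3 they were at Gfod1 (3.59, SE 0.81), Ap1m1 (2.64, SE 0.68) and Cdc42bpa (2.59, SE 0.67), and at Camk1d (-1.93, SE 0.45) and Frmd4a (-3.26, SE 0.78), each with an adjusted p of 1. Camk1d in the MPP3 interaction has the library pattern given above for the added step. No list passed for either interaction. A fit of the LT-HSC libraries alone called 16 regions, all lower, and without LT-HSC Dnmt3a;Npm1 replicate A 14 were called. In MPP3, 2 and 14 were called without Dnmt3a replicates A and B.

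No region was called in the same direction for both mutations and for either single mutation, which the counts all but fixed, since the double mutants had 1 call in LT-HSC and 0 in MPP3 and independent lists would share at most 0.026 regions. Double and single mutant differences share the WT libraries and so correlate without any effect. Across regions in LT-HSC, the correlation of the double mutant with Npm1 was 0.42 (covariance 0.16) against 0.5 (covariance 0.1) in simulated unchanged groups, and with Dnmt3a 0.43 (covariance 0.095) against 0.41 (covariance 0.099). In MPP3 it was 0.24 (covariance 0.022) with Npm1, against 0.41 (covariance 0.099), and 0.25 (covariance 0.053) with Dnmt3a, against 0.41 (covariance 0.098). Regions are not independent replicates, and the 2 WT libraries of a cell type could not be split, so part of any excess may come from the shared controls.

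Whether the effects differed between the cell types was tested directly. The Npm1 effect on the myeloid list was lower in MPP3 than in LT-HSC, with a median difference of -0.23 (camera adjusted p = 0.0162, adjusted p = 0.123 with an estimated correlation). The Dnmt3a effect was more positive in MPP3 for the Hox and Meis list (0.35, camera adjusted p = 0.00142, adjusted p = 0.515 with an estimated correlation) and the lymphoid list (0.44, camera adjusted p = 0.00512, adjusted p = 0.515 with an estimated correlation). Single regions did not pass: limma called 0 for Npm1, with 3337 at an unadjusted p under 0.05, and 0 for Dnmt3a, with 2953. Scaled to the library total, 4054 were called higher and 32 lower for Npm1, and 4 were called for Dnmt3a. Filip1l (-1.66, SE 0.26) and Zc3h7a (-1.61, SE 0.26), each with an adjusted p of 0.0507, and Ctbs (1.52, SE 0.32) and Wdr18 (1.53, SE 0.32), each with 0.104, led the Npm1 difference, and Tmem267 (2.75, SE 0.48) and Lyrm7 (-1.66, SE 0.34), each with 0.317, the Dnmt3a difference. For the Npm1 difference, 132 regions were called without MPP3 WT replicate B, 34 without MPP3 Dnmt3a replicate B and 15 without MPP3 Npm1 replicate A, and the myeloid list had an adjusted p of 0.0538 without LT-HSC Dnmt3a;Npm1 replicate B. For the Dnmt3a difference, 11 were called without MPP3 WT replicate A and 4 without MPP3 Dnmt3a replicate B. On the deposited scale, the 3 list medians were 0.96, -0.78 and -0.65 where all regions stood at 1.27 for Npm1 and -1.16 for Dnmt3a. The Hox and Meis difference was 0.18 (adjusted p = 0.0127) without LT-HSC Dnmt3a;Npm1 replicate B, and the lymphoid difference 0.28 (adjusted p = 0.0154) without MPP3 WT replicate B. With background subtracted none of the 3 passed and each median changed sign (0.37, -0.31 and -0.25, adjusted p = 0.158, 0.252 and 0.308), where all regions stood at 0.64 for Npm1 and -0.58 for Dnmt3a. With 1 region per gene the lymphoid difference turned to -0.05 (adjusted p = 0.732) and the myeloid difference was -0.08 (adjusted p = 0.357). The lymphoid difference also did not pass with loess (0.28, adjusted p = 0.12), with library enrichment as a covariate (0.10, adjusted p = 0.784) or near gene ends (0.49, adjusted p = 0.17), nor the myeloid difference with the covariate (-0.17, adjusted p = 0.165) or near gene ends (-0.23, adjusted p = 0.0677).

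Over the 17 planned comparisons and 13 lists, 14 of 221 camera tests passed, and 4 passed with an estimated correlation. The Hox and Meis list passed in 6 comparisons, the myeloid list in 4, the lymphoid list in 2, and the stem cell identity and the erythroid and megakaryocyte lists in 1 each. The interferon response list, which holds Mx1, passed in 0 (medians -0.22 to 0.28, smallest adjusted p = 0.214). The other lists that passed in 0 were those of genes cooperating in acute myeloid leukaemia (-0.11 to 0.05, smallest adjusted p = 0.391), early response genes (-0.07 to 0.10, 0.427), the cell cycle (-0.17 to 0.20, 0.214), DNA methylation and chromatin (-0.14 to 0.18, 0.296), and TNF and NF-kB signalling (-0.15 to 0.11, 0.235). The marker lists of other cells that a gate could hold also passed in 0: mast cells, basophils and eosinophils (-0.52 to 0.53, smallest adjusted p = 0.224, 4 genes with a tested region) and niche cells (-0.24 to 0.34, 0.0799).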

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

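The enrichment test and the tests of other splits were set before their results were seen, while the split of all 7 MPP3 against all 7 LT-HSC libraries belongs to a comparison added after the data were seen, and the alternatives with library enrichment as a covariate and with background subtracted were chosen only after the data were seen.

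The results below were picked out because a mutation's effect differed between MPP3 and LT-HSC in a direct test of that difference. The myeloid list differed by -0.23 for the Npm1 effect, and by -0.17 with library enrichment as a covariate (adjusted p = 0.165). The Hox and Meis list differed by 0.35 and the lymphoid list by 0.44 for the Dnmt3a effect, and with library enrichment as a covariate by 0.35 (adjusted p = 0.00255) and 0.10 (adjusted p = 0.784). None of the 3 passed with an estimated correlation, where the adjusted p values were 0.123, 0.515 and 0.515. For single regions, 2-group fits called 0 for either difference, while the highest of the other splits of the libraries called 301 for Npm1 and 204 for Dnmt3a. With a real count of 0, all 100 of 100 splits give as many by construction, so these splits decide nothing about chance.

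The higher Hox and Meis values in MPP3 Dnmt3a than in WT, with a list median of 0.37, could reflect the lower share of signal in tested regions of those libraries. The trend of signal with enrichment within groups of the 10 other libraries predicted -0.02 of the observed median, which met the bound written against enrichment. Lone libraries add nothing to that trend, and MPP3 Npm1 was the only MPP3 group behind it, so it cannot exclude enrichment. With library enrichment as a covariate the median was 0.31 (adjusted p = 0.00328). With background subtracted it fell to 0.09 (adjusted p = 0.0384), where all regions stood at -0.27. A Dnmt3a effect predicts a higher list in MPP3 Dnmt3a;Npm1 than in MPP3 Npm1, libraries not used in the pattern: the median there was 0.17 (camera p = 5.7e-04, p = 0.156 with an estimated correlation), in the predicted direction but with 1 double mutant library. A Dnmt3a effect, library enrichment and other differences between individual libraries therefore cannot be told apart here.

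Other splits of the 7 libraries of a cell type were counted for the averaged effects, with 2-group fits in place of the 8-group fit. The real splits called 0 regions for the Npm1 and the Dnmt3a effect in LT-HSC, where another split called 170, and 0 for both in MPP3, where another split called 2. With a real count of 0, all 35 of 35 splits give as many by construction, so these splits decide nothing about chance. For all 7 MPP3 against all 7 LT-HSC libraries, the real split called 251 regions and 2 of 100 splits gave as many, the real one included. That is under the 5% bound, but the 2-group fit is not the 8-group fit behind the 103 calls. The comparison was also added after the data were seen, so chance is not excluded for those calls. The highest other split called 1345, several times the real count, which points to a structure of the samples. Library enrichment, which the main principal component followed, is a candidate, but which libraries that split grouped was not examined.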

How the results depend on the processing

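The settings with a mean value of at least 20, 50 or 200, a pseudocount of 1 or 16, the deposited scale, quantile normalization, library weights, background subtracted, library enrichment as a covariate and unplaced contigs left out were chosen only after the data were seen, as was the comparison over all genotypes with all its alternatives. For LT-HSC Dnmt3a against WT and MPP3 Dnmt3a;Npm1 against WT, each with a lone mutant library, the count was 0 in 32 of 32 settings, which low power could also give. Counts within 1.5 times the reported one were found in 15 of 33 settings for LT-HSC Npm1 against WT, 12 of 32 for the averaged Npm1 effect in LT-HSC, and 10 of 30 for all genotypes. Values of single genes and lists stayed on their side of the threshold in 15641 cases, lost the call in 346 and gained one in 124. In these counts a list's direction is that of its test against the other regions, and the sign of a gene value past the threshold in neither fit was not counted. By the printed values, 995 such gene values changed sign. So did 29 medians of lists that had passed, 11 when scaled to the library total, 10 on the deposited scale, 7 with background subtracted and 1 with 1 region per gene. Regions at Meis1 (-1.53) and Npm1 (-1.68) changed sign and passed the threshold on the deposited scale in LT-HSC Npm1 against WT, where the median of all regions was -1.75. The planned count test alternative, GC correction and motif tests were not run. Unless a cause is given, the cause was not tested.

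Scaled to the library total, counts were 25 for WT MPP3 against LT-HSC, 11336 for LT-HSC Npm1 against WT (151 higher and 11185 lower), 5 for LT-HSC Dnmt3a;Npm1 against WT, 586 for MPP3 Dnmt3a against WT, 19 for MPP3 Dnmt3a;Npm1 against Dnmt3a, 2 for the MPP3 interaction. They were 5239 and 2 for the averaged Npm1 and Dnmt3a effects in LT-HSC, 1 for the averaged Dnmt3a effect in MPP3, 4086 (4054 higher and 32 lower) and 4 for the cell type differences of the Npm1 and Dnmt3a effects, and 393 for all genotypes, with 1 region shared between genotypes. That scale moved the median of all regions to -1.14, -0.75 and -0.74 for LT-HSC Npm1, MPP3 Dnmt3a and the averaged Npm1 effect in LT-HSC. With loess they were 175 for LT-HSC Npm1, 0 for LT-HSC Dnmt3a;Npm1 against WT, 1 for MPP3 Dnmt3a, 17 for the averaged Npm1 effect in LT-HSC, and 6 and 1 for the Npm1 and Dnmt3a cell type differences. On the deposited scale they were 14721 for LT-HSC Npm1 (11 higher and 14710 lower), 0 for LT-HSC Dnmt3a;Npm1 against WT, 29 for MPP3 Dnmt3a, 0 for either averaged effect in LT-HSC and 17 for all genotypes. With quantile normalization they were 0 for LT-HSC Dnmt3a;Npm1 against WT, 3 for the averaged Dnmt3a effect in LT-HSC, 12 for the Npm1 cell type difference and 278 for all genotypes.

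With no filter, counts were 451 for LT-HSC Npm1 (6 higher and 445 lower, 292 of them among the 1218), 10 for MPP3 Dnmt3a, 0 for either averaged effect in LT-HSC and 16 for all genotypes. At a mean of at least 20 they were 2 for WT MPP3 against LT-HSC, 3 for LT-HSC Dnmt3a;Npm1 against WT, 10 for MPP3 Dnmt3a and 0 for either averaged effect in LT-HSC. At 50 they were 3382 for LT-HSC Npm1 (826 higher and 2556 lower), 2 for LT-HSC Dnmt3a;Npm1 against WT, 2 for MPP3 Dnmt3a and 0 for either averaged effect in LT-HSC, and at 200 they were 417 for LT-HSC Npm1, 22 for the Npm1 cell type difference and 44 for all genotypes. A pseudocount of 16 gave 7 for the Npm1 cell type difference. At an adjusted p under 0.01 they were 37 for LT-HSC Npm1, 4 for all genotypes and 0 for LT-HSC Dnmt3a;Npm1 against WT and either averaged effect in LT-HSC. Tested against a fold of 1.5, they were 15 for LT-HSC Npm1 and 0 for these and for all genotypes. The stricter tests lower counts by construction.

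The replicate block gave 20 and 0 for the averaged Npm1 and Dnmt3a effects in LT-HSC. Each cell type's own libraries gave 16 for the LT-HSC interaction and 242 and 2 for the averaged Npm1 and Dnmt3a effects in LT-HSC, and the 4 WT libraries alone gave 1. Library weights gave 59 for WT MPP3 against LT-HSC, 5 for the averaged Dnmt3a effect in LT-HSC, 5 for the Npm1 cell type difference and 464 for all genotypes. Background subtraction gave 2077 for LT-HSC Npm1 (212 higher and 1865 lower), of which 461 were shared with the 1218, and 0 for LT-HSC Dnmt3a;Npm1 against WT, the averaged Npm1 effect in LT-HSC and all genotypes, with 7 list tests passing. Library enrichment as a covariate gave 0 for LT-HSC Npm1 and either averaged effect in LT-HSC, 1 for MPP3 Npm1 against WT and 20 for all genotypes. Without unplaced contigs, counts were 0 for the averaged Npm1 effect in LT-HSC and 2 for the Npm1 cell type difference. Of the list tests, 4 passed with an estimated correlation, 7 with fry, 31 with 1 region per gene and 29 with regions within 1 kb of a gene end. The 31 and 29 were set against all tested regions, so they may reflect the kind of region kept rather than the lists.

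With 1 library left out, counts ran from 0 to 13 for WT MPP3 against LT-HSC (highest without LT-HSC WT replicate A) and 84 to 2152 for LT-HSC Npm1 (without LT-HSC WT replicate A and MPP3 Dnmt3a replicate B). They ran from 0 to 99 for LT-HSC Dnmt3a;Npm1 against WT, 0 to 12 against Dnmt3a, and 0 to 14 for the LT-HSC interaction, each highest without LT-HSC Dnmt3a;Npm1 replicate A, and were 0 to 0 for LT-HSC Dnmt3a and MPP3 Dnmt3a;Npm1 against WT. Without MPP3 Dnmt3a replicate B the highest counts were reached for MPP3 Dnmt3a (0 to 368), MPP3 Dnmt3a;Npm1 against Dnmt3a (0 to 118), the MPP3 interaction (0 to 14), the averaged Npm1 effect in LT-HSC (0 to 122) and in MPP3 (0 to 13), and the averaged Dnmt3a effect in MPP3 (0 to 5). The range was 0 to 1 for MPP3 Npm1 and 0 to 132 for the Npm1 cell type difference, each highest without MPP3 WT replicate B, and 0 to 11 for the Dnmt3a difference, highest without MPP3 WT replicate A. The averaged Dnmt3a effect in LT-HSC ran from 0 to 37 (without LT-HSC Dnmt3a;Npm1 replicate A), all genotypes from 1 to 545 (without LT-HSC Npm1 replicate A and MPP3 Dnmt3a replicate A), and list tests from 8 to 16. The 8 were found without MPP3 Dnmt3a;Npm1 replicate B, the only library of its group, where 130 of the 221 list tests could be run and 6 of the 14 that had passed could not. The 8 others of the 14 all passed there, so no call was lost by that omission. Where this left a group with 1 library, that library was assumed to vary like the other groups.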

Other observations

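All tests of the Mx1 region and the values of the chromosome Y region were chosen only after their values were seen, as was the correction for enrichment applied to the Npm1 regions; the other tests of the Npm1 regions were set before their results were seen. The decision that a comparison subtracting the single LT-HSC Dnmt3a library settles nothing was also made after the values were seen, and it left open the test on lower regions that had met its bound against an Npm1 effect, the test on higher regions whose uncorrected value had met its prediction for an Npm1 effect, and the test that had met its prediction for accessibility like that of MPP3.

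The region at an end of Mx1 had normalized values of 405.3 and 281.5 in LT-HSC Npm1 and 115.7 and 145.8 in MPP3 Npm1, below the 10 other libraries, which ran from 448.8 in MPP3 WT replicate B to 1609.8 in MPP3 Dnmt3a replicate A. The difference of means was -2.01 on the log2 scale, with an exact two-sided permutation p of 1.0e-03 over 1001 groupings, the smallest they can give, for a region picked among 25129. A lower interferon response is a candidate explanation, but the interferon list had a median change of 0.08 in MPP3 Npm1 (camera adjusted p = 0.405) and of -0.22 in LT-HSC Npm1 (camera adjusted p = 0.419), which decides neither way. Extra copies of the Mx1 promoter in the Mx-Cre transgene could raise the signal in the other genotypes: of the 2 other tested regions within 100000 bp, 0 changed by more than 1 in MPP3 Npm1, the larger change being 0.36, but 2 neighbours are too few to decide. The labels name Mx-Cre for WT only, and write the Dnmt3a allele with fl and the Npm1 allele with frt. Single Npm1 is thus the only genotype whose label holds neither Mx-Cre nor an fl allele. Whether those donors carried Mx-Cre is not known, so a difference in it was not excluded for any comparison of Npm1 with WT. The explanations cannot be told apart.

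The chromosome Y region called lower with both mutations had values of 85.4 and 71.8 in LT-HSC Dnmt3a;Npm1, 182.5 in MPP3 Dnmt3a;Npm1 and 238.7 in LT-HSC Dnmt3a. In the other 10 libraries it ran from 270.4 in MPP3 Npm1 replicate B to 661.4 in MPP3 Dnmt3a replicate A. Another chromosome Y region (90739734 to 90740759), not called in any comparison, had 179.8 and 126 in LT-HSC Dnmt3a;Npm1, 150.4 in MPP3 Dnmt3a;Npm1 and 205.8 in LT-HSC Dnmt3a, and 225.4 to 567.8 in the other 10 libraries. The sex of the donors is not given in the sources used here. All libraries had signal in both regions, and whether either is specific to chromosome Y was not examined, so these values do not report sex.

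The 576 higher and 642 lower regions of LT-HSC Npm1 against WT may reflect lower library enrichment, since open regions then lose signal to the background. The trend within groups of the 10 other libraries predicted 0.45 of the higher and 0.35 of the lower median change, between the bounds set for either answer. It gave the right sign for 90.5% and 92.4% of these regions against 68.2% of uncalled ones. Called regions were picked for large differences, whose sign is less subject to noise, so that contrast decides nothing. The only LT-HSC pair behind the trend, Dnmt3a;Npm1, had nearly equal enrichment (log2 share -1.678 and -1.703). The trend therefore rests on MPP3 pairs and was extended to LT-HSC Npm1 libraries at -2.36 and -2.674, below all 10. The correction for enrichment given below used MPP3 libraries alone. With enrichment as a covariate 0 regions were called; the higher median went from 2.03 (SE 0.48) to 1.20 (SE 0.75) and the lower from -1.18 (SE 0.29) to -0.87 (SE 0.46), so the calls ended through smaller changes and wider errors. An Npm1 effect predicts the same shift when Npm1 is added to Dnmt3a, where the higher regions moved by 0.45 (matched uncalled sets 0.24 to 0.34, 0.16 against 0.05 to 0.16 after correction for enrichment) and the lower by -0.13 (matched sets -0.20 to -0.15, -0.02 against -0.09 to -0.04 after correction), and accessibility like that of MPP3, or MPP3 cells in the sort, predicts that the higher regions are open in MPP3, where the difference was 0.39 (matched sets 0.18 to 0.27, 0.21 against 0.08 to 0.18 after correction). The lower regions met the bound written against an Npm1 effect, moving less than their matched sets. Both comparisons subtract the 1 LT-HSC Dnmt3a library, whose own spread is unknown, so they were not taken to decide. The explanations cannot be told apart.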
